A study of Mus musculus with 12 samples.

How the data were processed

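Gene expression was measured in endothelial cells sorted from mouse lungs at postnatal day 5, in 3 groups of 4 libraries. Per the labels' protocols, RNA was extracted with Trizol, libraries were made from total RNA with the Lexogen QuantSeq kit, which reads a short stretch near the 3-prime end of each transcript, and sequencing used an Illumina NextSeq. Per the submitters' processing notes, Bowtie2, edgeR and the mm10 mouse genome build were used; the roles and versions of these tools are not given in the sources used here. The groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the 4 libraries of a group came from separate animals, so the p-values of single genes measure only the spread between these libraries.

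Each deposited table lists 24421 genes with a log2 value per gene, on a scale that the authors had already normalized. That the values are log2 and quantile normalized was worked out from the values: the 5000 highest ranks differed by at most 0.168 between libraries, and the highest value was 20.665 in each. Quantile normalization gives every library the same distribution, so it removes any difference in total output, and it can shift genes in a library that holds many transcripts of another cell type. Whole read counts could not be recovered and the depth is unknown. The number of genes above 0 ranged from 9850 in L12-ECKO replicate 3 to 13078 in L12-ECKO replicate 4, and the lowest value above 0 from 0.067 to 4.981, so low values are least precise in the former library. A gene listed at 0 may be one that was not sampled.

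2 kinds of rows were left out. In 2 libraries 27 genes stand under names turned into dates by a spreadsheet, and only the 24394 genes listed in all 12 tables were used. In 5 libraries (L12-ECKO replicates 2, 3 and 4 and L12YT-ECKO replicates 3 and 4) a block of 32 rows is displaced by 1 row. Over that block these libraries correlated with the WT mean at -0.0813 to 0.0367 in the same row and at 0.735 to 0.898 after moving by 1 row. The other 7 correlated at 0.707 to 0.891 in the same row. The rows of Rn45s and Rn4.5s are exchanged in the same 5 libraries. These 34 rows were not tested. The displacement marks a difference in how the authors processed these libraries, and it was treated as a batch: 0 of 4 WT, 3 of 4 L12-ECKO and 2 of 4 L12YT-ECKO libraries have it. By Xist and Ddx3y, 1 WT, 3 L12-ECKO and 1 L12YT-ECKO library came from females and the others from males. In L12-ECKO the female libraries are the ones with displaced rows, so within that group batch and sex cannot be told apart.

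The design fixed before the data were examined was a count test, with limma on log2(value + 1) as its replacement for normalized values. As the values were already on a log2 scale, they were used as deposited, with no second logarithm and no pseudocount. limma 3.58.1 in R 4.3.3 fitted a mean per group over all 12 libraries, with a variance prior that follows the mean expression and is robust to outlying genes (statmod 1.5.0). The fit had 9 residual degrees of freedom and a median of 10.1 prior degrees of freedom. The planned count-based filter could not be used either. Its fixed alternative took its place: a CPM of at least 1 in at least 4 libraries, with CPM computed from the deposited values raised from the log2 scale, which left 11634 genes. Several other settings, among them a filter at a value above 5 with values under 5 raised to 5, had already been run in a look at the data before this filter was settled. The setting reported departs from the fixed replacement in leaving out the second logarithm, with which 27, 1 and 4 genes were called instead of 56, 1 and 8. The counts of all settings are given with the other alternatives. P-values were adjusted by the Benjamini-Hochberg method over all genes tested and genes were called at an adjusted p under 0.05.

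29 gene lists with 498 entries were fixed before the data were examined, and 1 entry was not found in the tables. 28 lists had tested members. Each was tested with camera in limma, which asks whether the members of a list moved more than the other genes. It was run at a preset correlation of 0.01 and again with an estimated correlation. At the preset correlation its p measures the spread over genes, not that between libraries. With the estimated correlation the degrees of freedom also drop to the 9 residual ones. A call lost there need not come from correlation between members alone. The adjustment was over the 28 lists of a comparison. Named genes were chosen by a rule fixed in advance: the 4 targeted genes, Cyr61, Ctgf and Ankrd1, the 6 largest increases and the 6 largest decreases among called genes with a mean of at least 3 on the log2 CPM scale and no overlap between the groups, and up to 4 members of each list described. These were the called members with the smallest p or, where none was called, the 2 with the highest mean. 1 gene that this rule names is not reported here. Coordinates are from the GENCODE vM21 annotation of the same genome build.

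The procedure was tested on simulated data for L12-ECKO versus WT, with 200 of 11634 genes changed in each of 10 sets. It called 5% of genes changed by 1 on the log2 scale, 31% of those changed by 2, 41% of those changed by 3 and 55% of those changed by 4, and 4.57% of its calls were unchanged genes. A list shifted by 1 was called in 10 of 10 sets. These sets, and the simulated unchanged groups used for the overlaps, drew noise for each gene independently, with no batch. In the data the estimated correlation within a list reached 0.485, so these rates need not hold there. The alternatives tried were other filters, a floor under low values, a second logarithm, sample weights, no trend in the prior, the batch and sex as covariates, the displaced rows kept, a replicate block, fits of the 2 groups compared, and fits without single libraries or pairs of libraries. Figures were drawn with matplotlib 3.10.9.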

Results

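The series compared endothelial cells, sorted from the lungs of C57BL/6J mice at postnatal day 5, between 3 genotypes. The WT group held wild-type cells; whether these mice carried Cre or received an inducer is not stated. In L12-ECKO mice the Hippo pathway kinases Lats1 and Lats2 were deleted in endothelial cells with a VE-cadherin-CreERT2 driver. In L12YT-ECKO mice Yap1 and Wwtr1, which encode the transcriptional co-activators YAP and TAZ that these kinases restrain, were deleted as well. Each group had 4 libraries of 3-prime RNA sequencing. Values are the authors' quantile-normalized log2 expression, so a difference of 1 is a doubling, and the depth behind them is unknown. Between 9850 and 13078 genes lay above 0 per library. Correlations across genes (which are not independent replicates) ranged from 0.658 to 0.844 within groups and from 0.609 to 0.837 between groups. No 2 libraries held identical values. 5 libraries share a displacement of some rows, which divides the libraries into a batch of 7 and a batch of 5 and falls unevenly on the groups.

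The targeted genes were examined in every library first. Wwtr1 (chromosome 3, 57455649 to 57575910, protein coding) averaged 11.81 ± 0.19 in WT, 11.18 ± 0.71 in L12-ECKO and 8.81 ± 0.51 in L12YT-ECKO (SD, n = 4 each). All 4 L12YT-ECKO libraries lay below all others. Yap1 (chromosome 9, 7931999 to 8004596, protein coding) averaged 9.79 ± 0.24, 9.97 ± 0.53 and 7.72 ± 0.69 in the same order. Lats2 (chromosome 14, 57689662 to 57758388) averaged 8.93 ± 0.42, 9.93 ± 0.29 and 8.97 ± 0.43, and was not lower in either knockout group. Lats1 (chromosome 10, 7681214 to 7716460) was low and scattered: its values were 6.99, 5.32, 5.496 and 7.45 in WT, 7.40, 1.28, 0 and 5.78 in L12-ECKO, and 7.90, 0, 7.11 and 7.53 in L12YT-ECKO. The libraries read the 3-prime ends of transcripts, and the deleted exons are not given in the sources used here. A tag outside the deleted part checks nothing, so the Lats1 and Lats2 values neither bear out the labels nor speak against them.

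**Figure D1:**
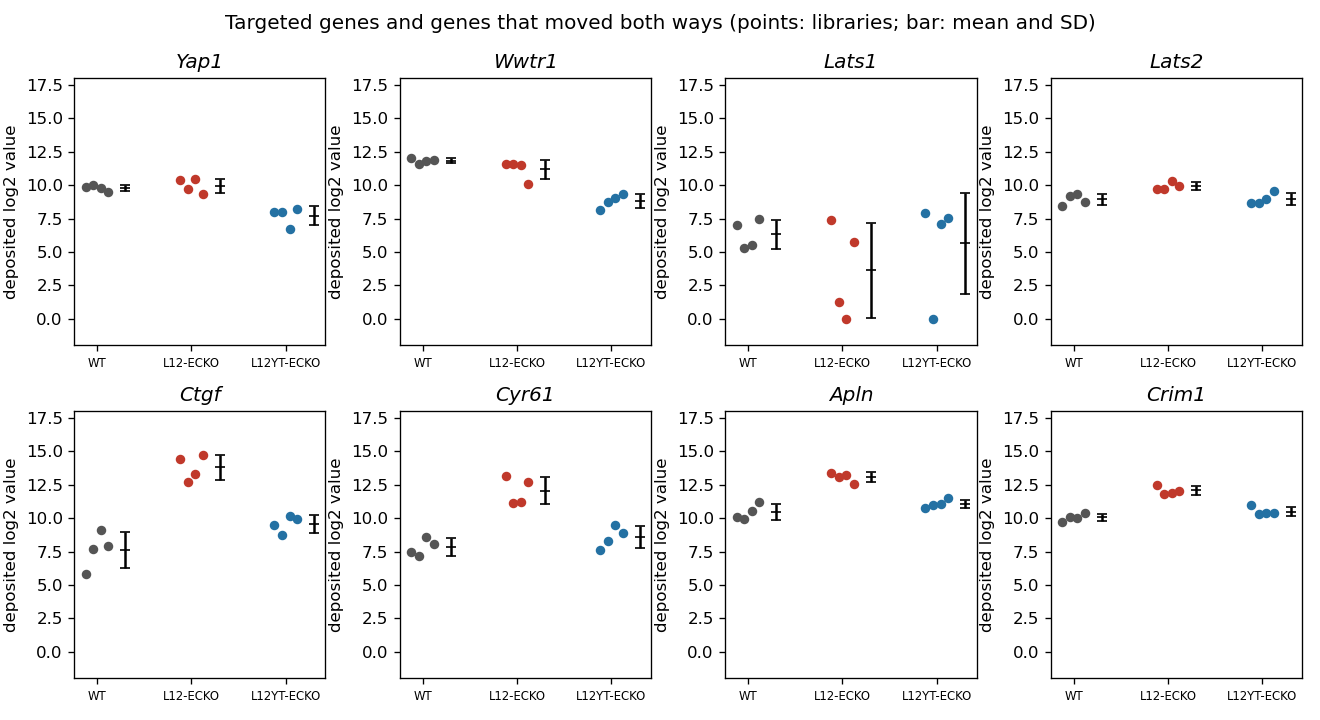
Deposited log2 values (y axis) of 8 genes in the 3 groups (x axis). Each point is a library, and the bar beside the 4 points of a group gives the mean and SD. Ctgf averaged 7.62 in WT, 13.80 in L12-ECKO and 9.57 in L12YT-ECKO.

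The comparison of L12-ECKO with WT asks what loss of both kinases does to these cells. Transcripts of Ctgf and Cyr61, which encode secreted matricellular proteins and are widely used as readouts of YAP and TAZ activity, both rose. Ctgf (chromosome 10, 24595442 to 24598683) averaged 7.62 ± 1.34 in WT and 13.80 ± 0.95 in L12-ECKO (SD, n = 4 each), a log2 difference of 6.18 (SE 0.617, limma adjusted p = 0.000378). Cyr61 (chromosome 3, 145646976 to 145649981) averaged 7.83 ± 0.65 and 12.05 ± 1.02, a difference of 4.22 (SE 0.507, limma adjusted p = 0.000378). The IGF-binding protein gene Igfbp3 rose by 3.99, the interferon-induced Isg15 by 3.96 and the kinase gene Sik1 by 3.36. The largest decreases met by the naming rule were the chloride channel family member Clic5, which fell by 2.03, the semaphorin gene Sema3c, which fell by 1.94, and the imprinted noncoding RNA H19, which fell by 1.79. Rasa1, a Ras GTPase-activating protein gene, fell by 1.68, the sodium channel gene Scn7a fell by 1.64 and Trim24 fell by 1.63. In all, limma called 56 of 11634 genes, 34 higher and 22 lower, and 55 of them met the rule's requirements on level and separation. Separation of 4 from 4 libraries arises by chance in 2.86% of unselected genes. Calling genes on these same libraries favours it, so the separation of called genes adds no support.

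These calls varied in firmness. Ctgf, Cyr61, Apln, Crim1 and Klf6 kept their calls without each of the 12 libraries in turn, whereas Sik1, Rasa1, Trim24 and Vegfa each lost it in 11 such fits and Gja4 and Cd93 in all 12. The count of 56 became 17, 12 and 27 without WT replicates 1, 2 and 4, and 24, 22, 36 and 31 without L12-ECKO replicates 1, 2, 3 and 4. It became 33 and 34 without L12YT-ECKO replicates 2 and 3, and 79 without WT replicate 3 was the highest. With the batch of displaced rows as a covariate, 15 genes were called, 11 of them among the 56, and with sex as a covariate 15, of which 13 were shared. The batch of 7 libraries holds a single L12-ECKO library, which was then assumed to vary like the other groups; it gave 42 calls, 15 higher and 27 lower, 10 of them shared. Without a trend in the prior variance 7 genes were called, 4 of them shared. The batch of 5 holds no WT library. Ctgf differed by 6.81 within the batch of 7 and by 6.04 with the batch covariate, and Cyr61 by 5.30 and 4.15. Both were called with the covariate, as were Igfbp3, Apln, Crim1, Klf6 and Scn7a. Clic5, Sema3c, H19, Rasa1 and Trim24 were not called with it, nor were Isg15, Bst2, Sik1, Mcam, Tgfb2, Vegfa, Sox17, Gja4 and Cd93. Their limma adjusted p ran from 0.11 for Sik1 to 0.37 for Bst2 and Trim24.

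Grouped by the lists fixed in advance, the YAP and TAZ target list had the largest median and the smallest p at the preset correlation in L12-ECKO versus WT; by the mean of its members (2.118) it lay below the interferon list (2.207), and in the batch of 7, whose only L12-ECKO library is replicate 1, the immediate-early list had the smaller p (5.52e-12 against 2.31e-08). Without that library, which had the highest median of the immediate-early list, the adjusted p of that list was 0.178. Of the 17 tested members of the YAP and TAZ target list 16 lay higher, with a median of 1.96. The YAP and TAZ target list was called (camera adjusted p = 1.65e-10, and adjusted p = 0.00368 with an estimated correlation). 5 members passed over all genes and 7 when adjusted over the list alone. Those with the smallest p were Cyr61, Ctgf, Igfbp3 and Crim1, a transmembrane protein gene, which rose by 2.01 (SE 0.274, limma adjusted p = 0.00168). Tgfb2 was the fifth, and it rose by 1.96. The list of p53 targets and apoptosis genes was also called (adjusted p = 1.81e-06, and adjusted p = 0.00502 with an estimated correlation): all 13 tested members lay higher, with a median of 1.08. None passed over all genes and 1 passed when adjusted over the list alone. Bax, a pro-apoptotic gene, differed by 1.04 and Cdkn1a, which encodes the cell-cycle inhibitor p21, by 1.27, without passing.

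Other lists were called in L12-ECKO versus WT only at the preset correlation. All 16 interferon response members lay higher, with a median of 1.87; Isg15 and Bst2 were called, Bst2 by 1.96, and 5 passed when adjusted over the list alone (adjusted p = 1.81e-06, but adjusted p = 0.0743 with an estimated correlation). Of 11 arterial markers 10 lay lower, with a median of -1.02. The transcription factor gene Sox17 fell by 1.16 and the gap junction gene Gja4 by 1.37, and 4 members passed when adjusted over the list alone (adjusted p = 0.000517, but adjusted p = 0.147 with an estimated correlation). General capillary markers had a median of -0.61, with Sema3c and Cd93 called and 4 passing when adjusted over the list alone (adjusted p = 0.000424, but adjusted p = 0.0723 with an estimated correlation). Immediate-early and stress genes had a median of 0.36, with library medians of 1.56, 0.72, -0.01 and -0.03 against WT in L12-ECKO replicates 1, 2, 3 and 4. Klf6 rose by 1.65, and 5 passed when adjusted over the list alone (adjusted p = 0.0014, but adjusted p = 0.502 with an estimated correlation). Tip cell and sprouting genes went both ways, with a median of 0.12. The angiogenic peptide gene Apln rose by 2.61, Mcam by 1.28 and Igfbp3 by 3.99, and adjusted over the list alone 6 were higher and 2 lower (adjusted p = 0.0396, but adjusted p = 0.388 with an estimated correlation).

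Markers of other cells were measured beside these lists. Mesenchymal markers had a median of -1.31 and were called lower, although the members with the highest mean, Eln and Col1a2, differed by 0.64 and -0.21 (adjusted p = 0.0386, but adjusted p = 0.231 with an estimated correlation). Endothelial inflammation genes had a median of 1.05, with Relb at 2.07 and Nfkbia at 0.72, neither called; no member passed adjusted over the list alone (adjusted p = 0.0455, but adjusted p = 0.445 with an estimated correlation). Immune markers were not called (camera adjusted p = 0.283), but were with the batch covariate (adjusted p = 9.98e-05). That fit leans on L12-ECKO replicate 1, the only L12-ECKO library without displaced rows. This library held S100a8 at 15.20 and S100a9 at 15.56, while the other L12-ECKO libraries lay between 0 and 7.71 for both. Without that library the adjusted p of the inflammation list was 0.415, that of the immediate-early list 0.178 and that of the tip cell list 0.258. Those of the p53 and YAP and TAZ target lists were 7.07e-06 and 5.52e-09. With the batch covariate the mesenchymal list had an adjusted p of 0.432. Liver transcripts went with the displaced rows, and so with the group: 15 liver genes, picked after their values were seen, averaged 4.87 to 7.48 in L12-ECKO replicates 2, 3 and 4, against 1.41 in replicate 1 and 1.09 to 2.97 in WT. In L12YT-ECKO they averaged 6.61 and 5.76 in replicates 3 and 4, against 1.66 and 2.5 in replicates 1 and 2. Markers of epithelial cells (adjusted p = 0.24) and of red cells and platelets (adjusted p = 0.111) were not called. The latter list had 8 of 9 members lower, with a median of -1.11, and was called lower with the replicate block (adjusted p = 0.0291) but not with the batch covariate (adjusted p = 0.944); the alpha-globin genes Hba-a1 and Hba-a2 had equal values in every library. The pan-endothelial list was not called (adjusted p = 0.179), with 18 of 26 members lower; adjusted over the list alone 6 were lower and 1 higher, and with the batch covariate the list was called lower (adjusted p = 0.0386).

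**Figure D2:**
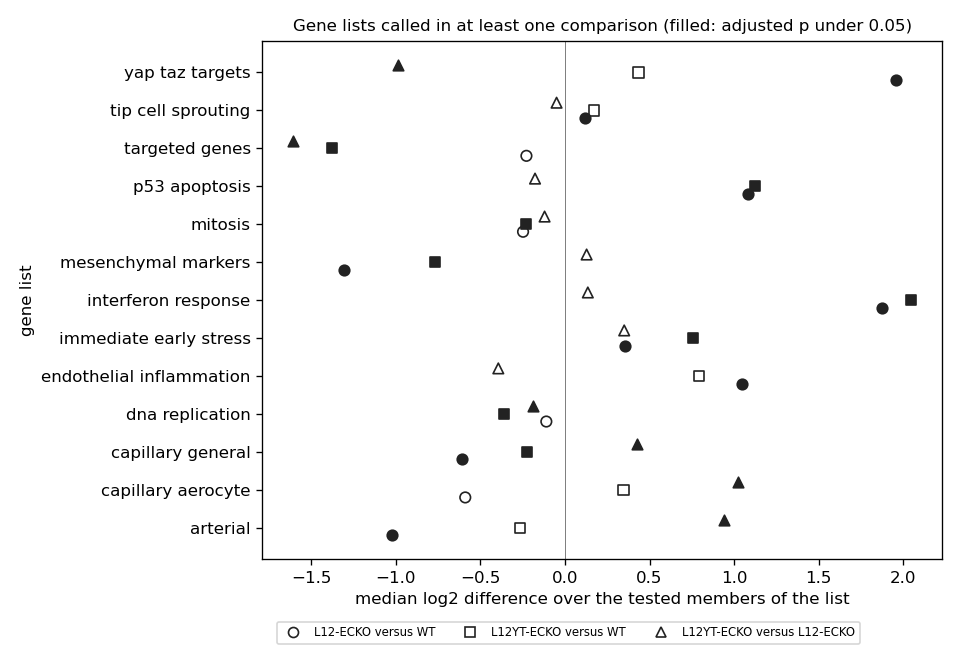
Median log2 difference over the tested members (x axis) of each gene list called in at least 1 comparison (y axis). Circles show L12-ECKO versus WT, squares L12YT-ECKO versus WT and triangles L12YT-ECKO versus L12-ECKO, filled where camera's adjusted p at the preset correlation was under 0.05. The YAP and TAZ target list lies at 1.96, 0.44 and -0.99.

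The comparison of L12YT-ECKO with WT asks what remains when YAP and TAZ are lost together with the kinases. Limma called 1 gene, Wwtr1, which fell by 3.001 (SE 0.35, adjusted p = 0.000662). It fell by 3.38 within the batch of 7 libraries and fell by 3.11 with the batch covariate, and was called in both. Without a trend in the prior variance limma called none, with 687 genes at an unadjusted p under 0.05. No gene was called higher, against 481 higher and 245 lower at an unadjusted p under 0.05. Chance alone puts a share of 0.05 of the 11634 genes tested there, so these unadjusted counts pick out no gene. Without WT replicate 1 the count of called genes was 3. Yap1 differed by -2.08 without passing (SE 0.406, limma adjusted p = 0.184). Ctgf differed by 1.95 (SE 0.617, limma adjusted p = 0.673) and Cyr61 by 0.75 (SE 0.507, limma adjusted p = 0.835), neither called. Ankrd1, another known YAP target, averaged 2.15 in WT, 2.38 in L12-ECKO and 2.28 in L12YT-ECKO, near the lower end of the values, and was called in no comparison.

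Lists gave a broader picture of L12YT-ECKO versus WT. The targeted genes were called lower (adjusted p = 2.54e-05, and adjusted p = 0.0226 with an estimated correlation). Among them Wwtr1 and Yap1 differed by -3.001 and -2.08, but Lats1 and Lats2 by -0.68 and 0.04. The same list was not called in L12-ECKO versus WT (camera adjusted p = 0.989). The p53 and apoptosis list was called higher (adjusted p = 1.31e-07, and adjusted p = 0.00562 with an estimated correlation), with all 13 members above WT, a median of 1.12 and 4 passing when adjusted over the list alone. Bax differed by 1.12 and Cdkn1a by 1.09. The interferon list had 15 of 16 members higher, a median of 2.05 and 8 passing when adjusted over the list alone (adjusted p = 8.36e-08, but adjusted p = 0.0544 with an estimated correlation); Rsad2 differed by 2.10 and Bst2 by 1.99. All 18 immediate-early and stress genes lay higher, with a median of 0.75 (adjusted p = 4.7e-10, but adjusted p = 0.203 with an estimated correlation); Klf4 differed by 0.64 and Jun by 0.38. Lists called lower only at the preset correlation were mitosis (adjusted p = 0.0158, but adjusted p = 0.295 with an estimated correlation) and DNA replication (adjusted p = 0.0213, but adjusted p = 0.586 with an estimated correlation). Their medians were -0.23 and -0.36, with 16 of 26 and 20 of 29 members lower. Top2a differed by -0.44 and Cenpa by 0.05, and Uhrf1 by -0.83 and Mcm5 by -0.32, none called. General capillary (adjusted p = 0.0213) and mesenchymal markers (adjusted p = 0.0314) were also called lower, each with an adjusted p = 0.223 with an estimated correlation. Cd93 and Cd36 differed by 0.0025 and -0.39, and Eln and Col1a2 by 0.43 and -0.32, none called. Within the batch of 7 libraries the adjusted p of these 2 lists was 0.0842 and 0.734. The YAP and TAZ target list was not called (adjusted p = 0.0746).

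The comparison of L12YT-ECKO with L12-ECKO asks which changes after loss of the kinases need YAP and TAZ. Limma called 8 of 11634 genes, 1 higher and 7 lower. Ctgf fell by 4.23 (SE 0.617, adjusted p = 0.019) and Cyr61 fell by 3.47 (SE 0.507, adjusted p = 0.00522). Wwtr1 fell by 2.37 and Yap1 by 2.25, as targeted genes. Apln (chromosome X, 48025146 to 48034853), an angiogenic peptide gene, fell by 2.01 (SE 0.296, adjusted p = 0.00522), Fam101b, annotated as Rflnb (chromosome 11, 76019194 to 76027782), fell by 1.74 and Crim1 fell by 1.58. Cldn5, a tight junction protein gene of endothelial cells, rose by 1.14 (SE 0.208, adjusted p = 0.0401). Wwtr1, Cyr61, Apln and Fam101b kept their calls without each of the 12 libraries in turn, whereas Cldn5 lost it in 11 such fits, Yap1 in 10, Crim1 in 8 and Ctgf in 4. The count was 4 without WT replicate 2 or L12YT-ECKO replicate 2, and 5 without L12-ECKO replicate 3 or L12YT-ECKO replicates 1 or 3. Within the batch of 7 libraries, where L12-ECKO has 1 library, 12 genes were called, 9 higher and 3 lower, 2 of them (Wwtr1 and Cyr61) among the 8. With the batch covariate 8 genes were called, 7 of them shared, and Ctgf had an adjusted p of 0.0548. Within the batch of 5, with 3 and 2 libraries, limma called none. There 325 genes had an unadjusted p under 0.05, where chance alone puts a share of 0.05 of the genes tested. There Ctgf differed by -3.53, Cyr61 by -2.49, Apln by -1.72, Fam101b by -1.55 and Cldn5 by 1.15, as against -5.35, -5.18, -2.49, -2.26 and 1.27 in the batch of 7.

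Among the lists, YAP and TAZ targets were called lower in L12YT-ECKO than in L12-ECKO, in 16 of 17 members and with a median of -0.99 (adjusted p = 1.46e-11, and adjusted p = 0.00256 with an estimated correlation). 3 members passed over all genes and 6 when adjusted over the list alone. The adjusted p was 1.26e-06 in the batch of 7 and 3.08e-10 in the batch of 5. The targeted genes were called lower (adjusted p = 4.49e-06, and adjusted p = 0.0118 with an estimated correlation). Among them Wwtr1 and Yap1 differed by -2.37 and -2.25, and Lats1 and Lats2 by 2.02 and -0.96, the latter 2 not called over all genes. Arterial markers were called higher, with 8 of 11 members higher, a median of 0.94 and 4 members passing when adjusted over the list alone (adjusted p = 0.000695, but adjusted p = 0.232 with an estimated correlation); Sox17 differed by 1.16 with an adjusted p of 0.0597 in limma, and Mgp by -0.44 with an adjusted p of 0.912. Aerocyte markers, of the capillary cells specialised for gas exchange, had a median of 1.02 (adjusted p = 0.0169, but adjusted p = 0.388 with an estimated correlation), although their member Apln fell. Without L12-ECKO replicate 1 camera's adjusted p for the aerocyte list was 0.143, in the batch of 5 it was 0.223 and with the batch covariate 0.0017. General capillary markers were called higher (adjusted p = 0.0498, but adjusted p = 0.271 with an estimated correlation) and DNA replication genes lower (adjusted p = 0.0466, but adjusted p = 0.489 with an estimated correlation). Cd93 and Cd36 differed by 0.75 and 0.74, and Uhrf1 and Fen1 by -0.19 and -0.68, none called. In the batch of 5 camera's adjusted p was 0.000573 for the arterial list, 0.114 for general capillary markers and 0.013 for DNA replication genes. With the batch covariate it was 0.000105, 0.0725 and 0.149 in the same order. None of these lists was called in the batch of 7, where L12-ECKO has 1 library. The p53 (adjusted p = 0.657), interferon (adjusted p = 0.74) and immediate-early lists (adjusted p = 0.116) were not called in this comparison. Immune markers had a median of -1.03, with 9 of 10 members lower, and were not called (camera adjusted p = 0.112). They were called lower with the batch covariate (adjusted p = 0.0017) and with sex as a covariate (adjusted p = 2.47e-05). Both fits lean on L12-ECKO replicate 1, the only male L12-ECKO library and the only one without displaced rows. There the median member lay 5.634 above WT, against 2.107, -1.49 and -1.663 in replicates 2, 3 and 4.

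5 genes rose in L12-ECKO versus WT and fell in L12YT-ECKO versus L12-ECKO: Ctgf, Cyr61, Apln, Crim1 and Fam101b. No gene did the opposite over all 12 libraries, but in the batch of 7 the count was 9, of which 2 rose and then fell and 7 did the opposite, and several other settings gave 1 or 2 such genes. The count was 3 without WT replicate 2 or L12YT-ECKO replicate 2. Both comparisons use the L12-ECKO libraries. Simulated unchanged groups gave 0.03 such genes on average over 100 sets and 1 at most, and independent lists would share 0.0205. With the L12-ECKO libraries split between the comparisons in all 6 ways, 0 to 4 genes were shared. The covariance of the log2 differences was -1.01 against -0.73 in the simulated sets, and -0.266 to -0.0423 with split libraries. Of the 56 genes called in L12-ECKO versus WT, 55 lay nearer to WT in L12YT-ECKO, which the choice of genes with large differences and the shared libraries favour even without any effect. In the 6 splits the genes called with some L12-ECKO libraries moved the opposite way against the others for 11 of 15, 21 of 30, 33 of 47, 36 of 57, 11 of 14 and 12 of 12 genes. No gene was called the same way in both knockout groups against WT, as Wwtr1 alone was called in L12YT-ECKO; without WT replicate 1 there were 2. Simulated sets and all 6 splits of the WT libraries also gave 0. The covariance of these differences was 1.18 against 0.731 simulated, and 0.267 to 0.332 with split libraries.

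**Figure D3:**
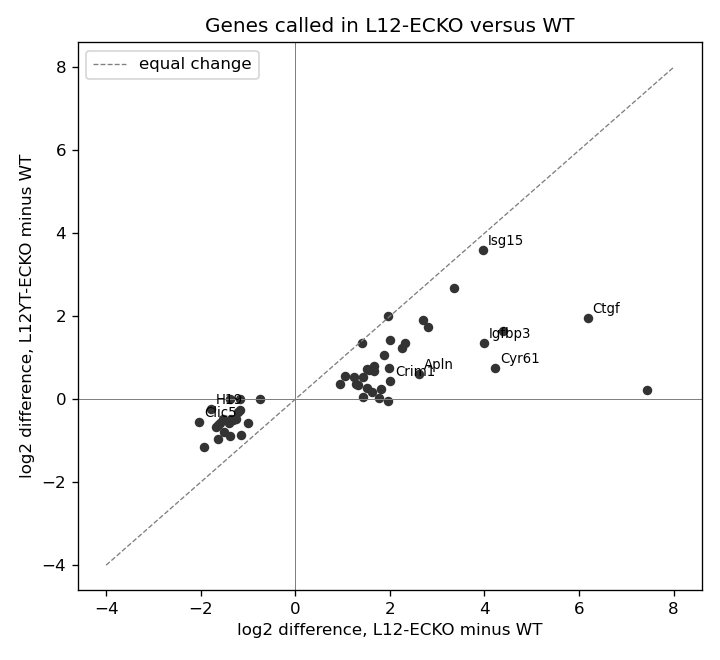
Log2 difference from WT in L12-ECKO (x axis) and in L12YT-ECKO (y axis) of the 56 genes called in L12-ECKO versus WT, 1 point per gene. Points on the dashed line changed equally; 55 of the genes lie nearer to 0 on the y axis than on the x axis, which selection on the x axis favours, and Ctgf lies at 6.18 and 1.95.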

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

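The patterns of neutrophil and liver transcripts and Treh were noticed in the data, and their first marker genes were picked after their values were seen; the tests here used other markers, with predictions set before those were measured, as were those for other splits of the libraries.

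66 groups of 4 libraries were examined for a library far from the others, and 5 had one; chance alone gives about 1 in 20. In L12-ECKO replicate 4 Wwtr1 was 10.11 against 11.49 to 11.56 in the others of its group. In L12YT-ECKO replicate 3 Yap1 was 6.694 against 7.96 to 8.204. In L12YT-ECKO replicate 2 Lats1 was 0 against 7.111 to 7.896. In L12-ECKO replicate 1 Clic5 was 9.598 against 8.806 to 8.919. L12-ECKO replicate 3 had 9850 genes above 0 against 12610 to 13080.

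In L12-ECKO replicate 1 immune transcripts were high despite the sort for endothelial cells: S100a8 was 15.198 and Lcn2 11.185. Of 14 neutrophil genes looked at first, 13 were highest there and G0s2 was not, but these had been picked after their values were seen. Of 12 other neutrophil markers 6 were above 0 in any library, and 5 of these 6 were highest in that library, among them Wfdc21 at 12.743; neutrophils or their RNA may be the source. Whether immune cells of every kind were present cannot be told: 4 of 11 other markers of B cells, T cells and macrophages were highest there, most of them near 0, so the test was too weak.

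Liver genes averaged 6.26 in the 5 libraries with displaced rows, against 1.09 to 2.97 in WT, over 15 genes picked after their values were seen. Treh, picked in the same way, averaged 10.47 against 0 to 8.83. Of 12 other liver markers 12 were higher on average in the displaced than in the other knockout libraries, so liver RNA that came with that batch may be the source. The knockouts themselves are argued against: over these markers 0 of the 3 knockout libraries without displaced rows lay above the highest WT library, with means of 0.375 to 0.557 against 2.63 to 5.23 in the displaced libraries. Where the RNA entered stays open.

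Other splits of the same libraries bear on the counts of called genes. For L12-ECKO versus WT 1 of 35 splits, the real one, gave 56 genes, and the highest other gave 1. For L12YT-ECKO versus L12-ECKO 1 of 35, again the real one, gave 8, with 1 in the highest other. Chance is argued against for both counts but not excluded, as 1 of 35 is the smallest share these splits can give. The other splits also mix the genotypes, which widens the spread within their groups for genes that differ. For L12YT-ECKO versus WT 4 of 35 gave at least 1 gene and the highest other gave 2, in a split with both L12YT-ECKO libraries with displaced rows on one side, as in the real split, so chance cannot be excluded for a count of 1. This bears on the count alone. The gene called in the real split was Wwtr1, which was deleted in L12YT-ECKO by design and lay lower there than in every other library.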

How the results depend on the processing

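Fits without single libraries, without both smaller L12-ECKO files, of 2 groups or without a filter, the replicate block and the estimated correlation were planned; the second logarithm is the fixed replacement taken literally; all other settings were chosen after seeing the data, and counts of several were known before the filter was settled. The count for L12-ECKO versus WT, 56, was 87 (53 higher, 34 lower) with a value above 5 in at least 4 libraries and values under 5 raised to 5, 21 without a filter, 11 without both smaller L12-ECKO files (replicates 1 and 2), 27 with a second logarithm, 24 with sample weights and 7 without the trend. It was 15 with displaced rows or sex as a covariate, 9 with both (all higher), 14 without L12-ECKO 1 and 3, and 26 in the 2-group fit. All 56 genes were among the 87. The count for L12YT-ECKO versus L12-ECKO, 8, was 1 without L12-ECKO 1 and 2, 4 with a second logarithm, 21 with weights, 3 without the trend, 5 with sex, 4 with sex and displaced rows, 0 in the 5 libraries with displaced rows (325 genes at an unadjusted p under 0.05 in limma), 0 without L12-ECKO 1 and 3 (554 unadjusted), and 4 in the 2-group fit. That for L12YT-ECKO versus WT, 1, was 0 without the trend (687 unadjusted). Chance alone puts a share of 0.05 of the genes tested under an unadjusted p of 0.05, so the unadjusted counts pick out no gene. The 5 genes changed in opposite ways became 0, 3, 2, 3, 1, 9 and 0 without L12-ECKO 1 and 2, with a second logarithm, without the trend, with sex, with sex and displaced rows, in the 7 libraries without displaced rows (2 rose first, 7 fell first), and without L12-ECKO 1 and 3. The cause was not tested, except that fits of fewer libraries hold fewer residual degrees of freedom. With an estimated correlation 2 lists were called in each comparison instead of 9, 8 and 6. The 8 lists of L12YT-ECKO versus WT became 5 with values under 5 raised to 5, and the 9 of L12-ECKO versus WT became 15 in the 7 libraries. Leaving out single libraries gave 12 to 79 genes, 1 to 3 and 4 to 9 for the comparisons with WT of L12-ECKO and L12YT-ECKO and for L12YT-ECKO versus L12-ECKO; 3 to 6 and 0 to 2 for the opposite and same overlaps; and 6 to 9, 4 to 9 and 4 to 8 lists.

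The log2 difference of Lats1 in L12-ECKO versus WT turned to 1.09 in the 7 libraries and that of Yap1 to -0.26 without L12-ECKO 1 and 3; neither was called. Of 1022 recomputed values of 35 named differences 663 kept direction and side of the threshold, 357 lost the call and 2 changed sign. The 35 include Lats1, Lats2, Yap1 and Wwtr1 in L12-ECKO versus WT, which were not called at first and so could not lose a call. Of 696 values for 23 called lists 585 kept the call and 111 lost it. No pairing of the libraries by replicate number was seen: same-numbered libraries' deviations correlated at -0.0467 to 0.0583 over 12 pairs, and 4 of 12 libraries correlated best with their own number. Correlations over all genes cannot exclude a pairing. With the replicate block 43, 1 and 6 genes and 10, 8 and 6 lists were called. Fits that need counts (other size factors, library totals, DESeq2 and voom with quality weights) were not run, nor was setting absent genes to 0, as those genes stand under other names. Unknown depth limits low genes, most of all in L12-ECKO replicate 3.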

Other observations

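The tests of batch, sex and dependence on Yap1 and Wwtr1 in this part were chosen after the members' values in the 12 libraries had been seen; the lists and the estimated correlation were planned.

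The interferon and p53 lists lay higher than the WT mean in every knockout library. The immediate-early list did so in all 4 L12YT-ECKO libraries, but in L12-ECKO only in replicates 1 and 2. In L12-ECKO its median member lay at 0.7184, -0.00725 and -0.02713 in the 3 libraries with displaced rows and at 1.56 in the other, so that it was not higher with the displacement. At the preset correlation it stayed called with the batch covariate (adjusted p = 2.2e-06 in L12-ECKO and 1.03e-12 in L12YT-ECKO), with sex (5.79e-06 and 3.08e-10) and in the 7 libraries (5.52e-12 and 9.29e-10). It was not called with an estimated correlation (adjusted p = 0.502 in L12-ECKO and adjusted p = 0.203 in L12YT-ECKO) or, in L12-ECKO, without replicate 1 (adjusted p = 0.178). With an estimated correlation the p53 list stayed called in both comparisons with WT. The interferon list did not (adjusted p = 0.0743 with an estimated correlation in L12-ECKO, and adjusted p = 0.0544 with an estimated correlation in L12YT-ECKO).

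The batch of displaced rows is argued against as the whole cause for 2 lists: in the 7 libraries without it the median knockout library lay 2 above WT for interferon (1.84 to 2.09, WT up to 0.865) and 1.34 for p53 (1.33 to 1.36, WT up to 0.257). The greater number of females is argued against likewise, with 1.71 (1.24 to 2.23, WT up to 0.378) and 1.28 (0.902 to 1.46, WT up to 0.412) in males alone. In L12-ECKO both tests rest on replicate 1, the only male library and the only one without displaced rows. They clear the other L12-ECKO replicates of neither cause, and replicate 1 was high in neutrophil transcripts. For the immediate-early list neither the batch, with 1.11 (0.482 to 1.56, WT up to 0.425), nor sex, with 1.01 (0.414 to 1.36, WT up to 0.547), can be excluded by this test, as the lowest knockout library did not clear the highest WT library by the SD of WT. WT and L12YT-ECKO each held 1 female library, which argues against a greater number of females as the cause in L12YT-ECKO. The batch stays open there, and both stay open in L12-ECKO. A change that Yap1 and Wwtr1 carry is argued against for interferon and p53. Over the L12YT-ECKO libraries their median member lay on average 0.448 (SE 0.44) and -0.0692 (SE 0.0995) from the gene means of L12-ECKO. Loss of 0.5 of the rise would give -0.936 and -0.54. The L12-ECKO libraries' own medians enter the SE but were not subtracted from these values. Over the members the group differences had medians of 0.135 and -0.177. The immediate-early list, at 0.344 (SE 0.259) against -0.178, passed this test only barely. With those medians not subtracted, the question stays undecided for that list. Cre or its induction, loss of Lats1 and Lats2 independent of YAP and TAZ, and the handling of WT and knockout mice may each account for the rise of these lists and were not tested: whether WT carried Cre or received an inducer is not stated.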
